A study of Daphnia magna with 84 samples.

How the data were processed

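Whole-animal RNA sequencing of the water flea Daphnia magna was analysed in 84 libraries, each from 1 animal. Per the labels, animals were fed green algae that had first been held in a coal ash mixture at 1 of 6 concentrations, which are named by their mercury content (4, 1, 0.25, 0.12, 0.06 and 0.015 nM Hg/L), or were in the group at concentration 0, and were taken at day 6, 10, 17 or 24. The 7 concentrations and 4 days give 28 groups of 3 animals. Groups were taken from the concentration and day of each sample's labels. Replicates were numbered in accession order, which names a library and pairs none. 1 library labelled 0.06 nM Hg/L at day 24, replicate 3, carries a number in its title that lies among those of the 0.12 nM Hg/L animals; it was kept as labelled. 1 title number appears on 2 libraries, both labelled 0.12 nM Hg/L, at days 6 and 24; they were kept as 2 animals, and the labels do not say why the number is shared.

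Per the labels' protocols, RNA was extracted from single animals, ribosomal RNA was depleted and the libraries were made with a kit that marks strand. Reads were aligned with STAR 2.7.5b, per the submitters' processing notes. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here. The deposited table holds whole-number counts per gene model and library, not normalized, and per the file headers it gives the exons of each model on contigs and scaffolds, from which the coordinates printed here are taken. Overlapping, antisense and near-identical models can therefore share counts in a way that could not be checked. The table holds 27350 gene models (26646 with IDs that begin with APZ42 and 704 with IDs that begin with ENSRNA), of which 3363 had no counts in any library. It pairs no ID with a gene name, and 0 of its IDs matched the reference gene table of assembly ASM2063170v1.1. Gene models are therefore given by ID, and what they encode is not stated. For the same reason the 30 gene lists planned by descriptive name could not be formed, and the tests of gene lists as sets were not run.

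Counts were analysed in R 4.3.3 with edgeR 4.0.16. Gene models were filtered with filterByExpr over the 28 groups at its minimum count of 10, which left 12685, and scaled with the trimmed mean of M-values (TMM). A model with 1 mean per group was fitted to all 84 libraries (56 residual degrees of freedom) with edgeR's quasi-likelihood fit, with robust shrinkage. Each comparison was a contrast of group means: each concentration against 0 averaged over the 4 days, 4 nM Hg/L against 0 within each day, the lower concentrations against 0 within each day (20 contrasts, each adjusted on its own, with their calls summed), any difference among the 7 concentrations within each day, the slope on concentration rank averaged over days, the difference of that slope between days, and days 10, 17 and 24 against day 6 averaged over concentrations. P-values were adjusted by Benjamini-Hochberg over all models tested, and an adjusted p below 0.05 was called. Adjusted p-values printed without another tool's name come from this test. Log2 changes are the fitted contrasts, and their standard errors (SE) were derived from the change and its F statistic. CPM values were computed by edgeR from the counts and the TMM-scaled library size. The quasi-likelihood fit of edgeR 4 without a separate dispersion step was chosen over the older fit after both had been run, on run time, so this part of the test was not fixed in advance. The older fit is among the alternatives, and it gave lower counts for every concentration against 0 averaged over days (4 in place of 239 at 0.12 nM Hg/L, for example) and for the day 24 comparison of 4 nM Hg/L with 0 (678 in place of 2385).

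The comparisons, the kind of test (edgeR's quasi-likelihood F test, without naming the dispersion step), the rule for named models and most alternatives were fixed before the data were examined. Because no model has a descriptive name, the rule names the 2 highest and 2 lowest models of each single contrast by log2 change among those called with a mean of at least 5 CPM in its libraries, and for averages over days also with the same sign at all 4 days. Joint tests name none. Alternatives fixed in advance were DESeq2 size factors, no filter, DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), a fit of only the libraries compared, 2 surrogate variables (sva 3.50.0), the concentration itself as the trend score, and leaving out each library in turn. Chosen after seeing the data were the older fit, removal of the 5 most abundant gene models, leaving out the 3 libraries of concentration 0 at day 24, leaving out the 5 libraries with under 500000 counts outside those 5 models, the log2 share of counts outside them as a covariate, and leaving the 3 libraries out of the comparisons only, with all 84 fitted. Where those 3 libraries were left out, each concentration was compared with 0 over days 6, 10 and 17 only (15 contrasts in place of 20 for the lower concentrations), and day 24 entered the trend and the comparison with day 6 through the exposed concentrations alone.

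Runs of neighbouring models were counted over the tested models in their order on each contig or scaffold and compared with 1000 shuffles of the calls over the models. Classes of gene models were compared with Fisher's exact test, 2-sided and adjusted over 24 tests. A fold against a group with no counts was bounded with a floor of 3 counts over the group. Counting intervals and floors use counts pooled over the animals of a group, so they leave out the spread between animals. The reads carry no molecular identifiers, so repeated reads of 1 molecule count as separate. To find a library deposited more than once, same-group libraries were compared by a chi-square statistic of their counts. The lowest value per degree of freedom among the 84 pairs was 3.57, so no pair was counted as 1 sample; separate animals differ by more than counting noise in any case.

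The scripts were tested on simulated data, with 200 models changed by known amounts at 4 nM Hg/L on every day. Counts for the real gene models were drawn from their overall means, the TMM-scaled library sizes and the estimated dispersions. Every simulated library thus had the same composition apart from the changed models. The higher share of the most abundant models in the libraries of concentration 0 at day 24 was not simulated, so the rates of false calls below do not cover it. Models were also drawn independently of each other, so differences between animals that many models share are not covered either. Shuffled splits of the real libraries, given below, reached 1855 calls for day 10 and 723 for day 17 against day 6, with a median of 0. For 4 nM Hg/L against 0 at day 24, 524 of 12136 unchanged models (4.32%) were called with TMM, and the median log2 change of the unchanged models was 0.68. With the simulated scaling in place of TMM, 140 of them were called. For 4 nM Hg/L against 0 averaged over days, 139 of 12136 unchanged models were called with all libraries, and 10 were called in the average over days 6, 10 and 17 when the 3 libraries of concentration 0 at day 24 were left out. In that second fit 43 of 50 models raised by a log2 change of 2 were recovered, and 17 of 50 raised by a log2 change of 1. For the trend averaged over days, 75 of 12136 unchanged models were called with all libraries and 9 without those 3 libraries. For day 10 and for day 17 against day 6, 0 of 12136 unchanged models were called with all libraries; for day 24 against day 6, 47 were called (median log2 change of the unchanged models -0.16), and 0 without the 3 libraries. The test was not changed after these simulations, and values without the 3 libraries are printed beside it.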

Results

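The transcriptomes of 84 single Daphnia magna were measured after dietary exposure to a coal ash mixture. Daphnia magna is a freshwater crustacean that is widely used in toxicity testing. The study asked how exposure at 6 concentrations, named by their mercury content, changed expression from that at concentration 0 at days 6, 10, 17 and 24. Each of the 28 groups held 3 animals. Total counts ranged from 7127253 to 27952023 per library with a median of 17553926.

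Most counts fell in 5 gene models, called the dominant models here. APZ42_024615 (scaffold01685, 306 to 1983, 5 exons) held 29.1% of all counts, and its neighbour APZ42_024616 (scaffold01685, 1997 to 8445, 2 exons) held 15.2%. APZ42_004030 (contig22920, 446 to 963, 3 exons) held 19.6%, APZ42_003886 (contig22203, 1 to 204, 1 exon) 18.3% and APZ42_003885 (contig22202, 194 to 730, 1 exon) 9.61%. All other models together had between 25520 and 2596374 counts per library, with a median of 1463484, and this is the depth behind every other value. That depth was lowest in the animals at concentration 0 and day 24, where it was 64510 ± 50735 counts (SD, n = 3) against 1740587 ± 274040 (SD, n = 3) at 4 nM Hg/L on that day. In those 3 libraries APZ42_004030 alone held 63.3% to 92.6% of counts, compared with 12% to 44.1% in the other 81. The next lowest group was 0.12 nM Hg/L at day 24, with 518723 ± 99781 counts (SD, n = 3). At day 6 the depth was 1055480 ± 780777 counts (SD, n = 3) at 4 nM Hg/L and 2311727 ± 248254 at concentration 0. Since the day 24 animals at concentration 0 enter every average over days, the counts they enter are also given without them, a choice made after seeing the data. Without them the comparisons change too: each average against concentration 0 then covers days 6, 10 and 17 only, the trend at day 24 and the day 24 comparison with day 6 cover the exposed concentrations, and no comparison with concentration 0 exists at day 24.

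**Figure D1:**
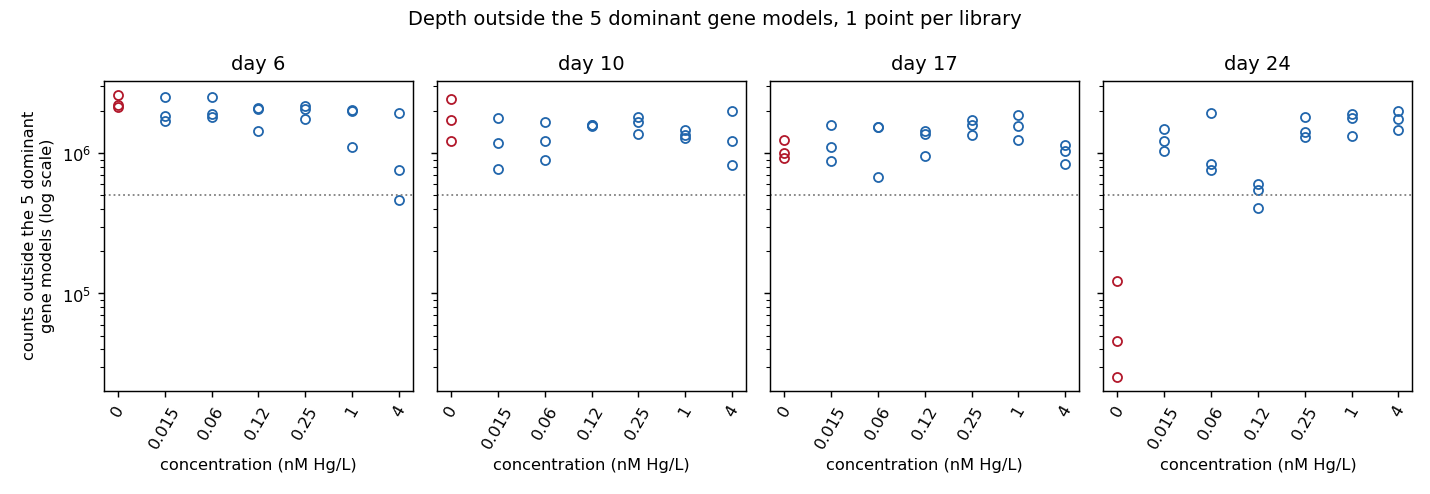
Counts outside the 5 dominant gene models (vertical axis, log scale) by concentration in nM Hg/L (horizontal axis) on each day, with 1 point per library, red for concentration 0 and blue for exposed animals, and a dotted line at 500000 counts. The 3 animals at concentration 0 and day 24 lie at or below 121871 counts, under every other library.

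Days were compared first, as days 10, 17 and 24 against day 6 averaged over the 7 concentrations. Libraries of different days also differed in depth, which was not separated from day. Total counts ranged from 19097292 to 27952023 at day 6 and from 11615188 to 16675899 at day 17. The median outside the dominant models was 1992461 at day 6, 1469071 at day 10 and 1248656 at day 17. At day 24 it was 1371471 without the animals at concentration 0. APZ42_029433 (scaffold02581, 538832 to 543855, 2 exons) was high at day 6 and low afterwards: it averaged 14.5 ± 11.3 CPM (SD, n = 21) at day 6, 0.179 ± 0.262 at day 10, 0.857 ± 2.01 at day 17 and 0.674 ± 1.96 at day 24. APZ42_014845 (scaffold00512, 128468 to 129323, 2 exons) fell from 23.9 ± 18.0 CPM (SD, n = 21) at day 6 to 0.888 ± 2.08 at day 17 and 0.536 ± 1.00 at day 24. APZ42_031767 (scaffold02994, 752936 to 753605, 3 exons) fell from 11.2 ± 7.67 CPM (SD, n = 21) at day 6 to 0.383 ± 1.16 at day 10. In the other direction APZ42_031291 (scaffold02916, 16584 to 17934, 4 exons) rose from 0.124 ± 0.142 CPM (SD, n = 21) at day 6 to 23.3 ± 26.1 at day 10. APZ42_029452 (scaffold02581, 762958 to 768611, 2 exons) rose from 0.300 ± 0.564 to 35.3 ± 34.7 CPM (SD, n = 21) over the same days.

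At day 17 the models with the highest change were APZ42_017878 (scaffold00725, 175486 to 178545, 4 exons), which rose from 0.764 ± 2.67 to 30.2 ± 36.1 CPM (SD, n = 21), and APZ42_034082 (scaffold03326, 313232 to 317905, 4 exons), which rose from 0.768 ± 1.93 to 26.3 ± 24.8. At day 24 they were APZ42_007214 (contig44053, 1 to 308, 1 exon), at 0.355 ± 0.936 CPM (SD, n = 21) on day 6 and 22.7 ± 27.3 on day 24, and APZ42_001476 (contig07021, 1 to 582, 2 exons), at 0.338 ± 0.794 and 31.4 ± 41.7. Animals differed widely in the rising models, as their SDs show, and single animals carried much of the low means. Without its highest animal the day 6 mean was 0.197 CPM for APZ42_029452, 0.184 for APZ42_017878, 0.384 for APZ42_034082, 0.169 for APZ42_007214 and 0.184 for APZ42_001476. In the same way APZ42_029433 averaged 0.530 CPM at day 17 and 0.267 at day 24, APZ42_031767 0.134 at day 10 and APZ42_014845 0.518 at day 17. In log2 terms the day 10 changes were 7.47 (SE 0.79, adjusted p = 1.3e-11) for APZ42_031291 and -6.57 (SE 0.63, adjusted p = 3.5e-13) for APZ42_029433. The day 17 changes were 6.31 (SE 0.90, adjusted p = 6.2e-08) for APZ42_017878 and -5.92 (SE 0.54, adjusted p = 3.1e-14) for APZ42_014845. The day 24 changes were 7.53 (SE 0.84, adjusted p = 3.3e-11) for APZ42_007214 and -6.82 (SE 0.60, adjusted p = 3.5e-15) for APZ42_014845. That model had 0 counts at 1 nM Hg/L on day 24, so this average includes a fold over a group with no counts and gives no exact size.

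**Figure D2:**
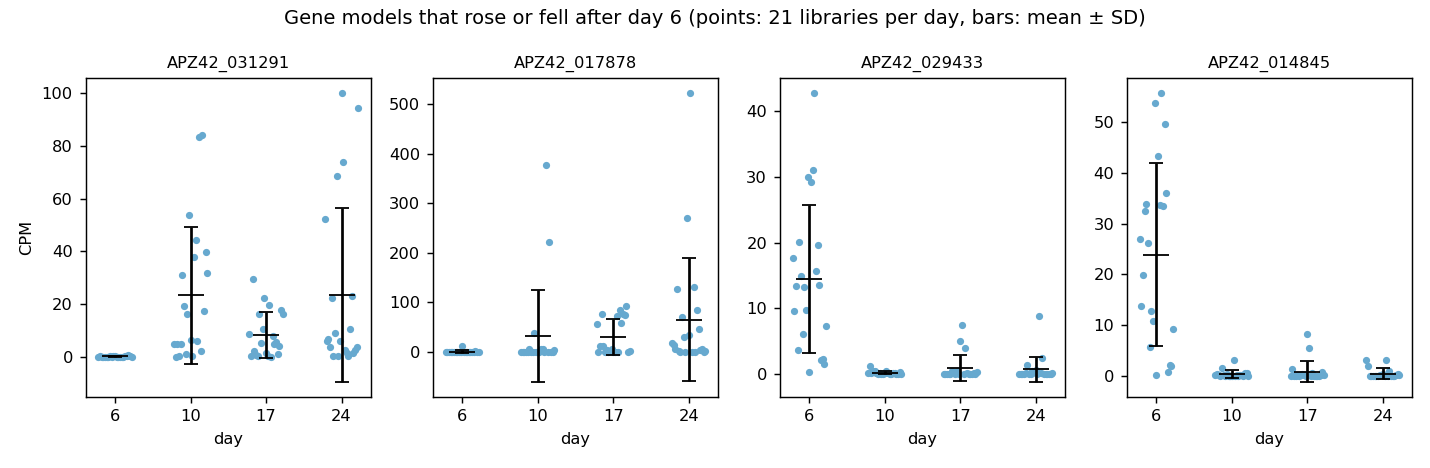
CPM (vertical axis) by day (horizontal axis) of 4 gene models named by the fixed rule, with 1 point per library, 21 per day, and bars for the mean ± SD. APZ42_031291 and APZ42_017878 averaged under 1 CPM at day 6, where 1 animal reached 12.4 CPM of APZ42_017878, and varied widely between animals later, whereas APZ42_029433 and APZ42_014845 averaged 14.5 and 23.9 CPM at day 6 and under 1 CPM later.

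At day 10, 5443 of 12685 tested models differed from day 6 by edgeR's quasi-likelihood test, 3065 higher and 2378 lower. At day 17, 4165 differed, 2228 higher and 1937 lower, and at day 24, 4680 differed, 1383 higher and 3297 lower. Without the day 24 animals at concentration 0 there were 5758 at day 10 and 4512 at day 17, and the day 24 split was 2522 higher and 2343 lower of 4865. With all libraries the day 24 split was 2455 higher and 1878 lower by DESeq2 and 2965 and 2524 by limma-voom, while 39.3% were higher with DESeq2 size factors, so the direction of the day 24 majority turned with the tool as well as with those 3 libraries. It was 2323 higher and 2245 lower when all libraries were fitted and the 3 were left out of the comparison only. 3526 models were called at day 24 both with and without them.

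Models that changed in the same direction after day 6 lay next to each other, a pattern examined after the values were seen. On scaffold02581, 16 neighbouring tested models between 359075 and 438174 were all higher at day 24 than at day 6 when the 3 libraries were left out, with a median log2 change of 5.21 and a range from 1.85 to 6.61; they had 3 exons at the median, and 6 lay on the plus and 10 on the minus strand. With all libraries, 9 neighbours between 405348 and 438174 were called at day 24, with a median of 5.57. Of that stretch, 10 neighbours between 404268 and 438174 were higher at day 17 with all libraries, at a median log2 change of 4.98. On scaffold01409, 10 neighbours between 275665 and 320150 were higher at day 10 (median 4.61), and 11 between 282814 and 358287 were higher at day 17 (median 4.56). On scaffold00626, 10 neighbours between 1240715 and 1334457 were higher at day 10 (median 1.56). Without the 3 libraries, 11 neighbours on scaffold01409 between 283622 and 361450 (median 5.30) and 10 on scaffold00568 between 40026 and 115531, all on the plus strand (median 4.09), were higher at day 24. On scaffold00687, 9 neighbours between 880104 and 903590 were lower at day 17, with a median log2 change of -1.91. Falling stretches at day 24 with all libraries were 9 neighbours on scaffold01581 (median -1.76) and 8 on scaffold00626 (median -1.28). Without the 3 libraries no falling stretch at day 24 held 8 or more neighbours. Runs of at least 5 neighbours called in the same direction numbered 42 at day 10, 21 at day 17 and 32 at day 24, against means of 7.46, 1.88 and 8.19 in 1000 shuffles of the calls (permutation p = 0.001 each, the smallest those shuffles can give). Without the 3 libraries they numbered 46, 23 and 35, against means of 9.63, 2.80 and 4.01. These counts pool both directions. The longest run in any shuffle held 10, 10 and 11 models with all libraries and 12, 12 and 9 without the 3. Of the stretches named here only the 11 at day 17 with all libraries and the 10, 11 and 16 at day 24 without the 3 were longer. The shuffles are over gene models, which are not independent replicates, and reads shared between near-identical neighbours could not be told apart.

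**Figure D3:**
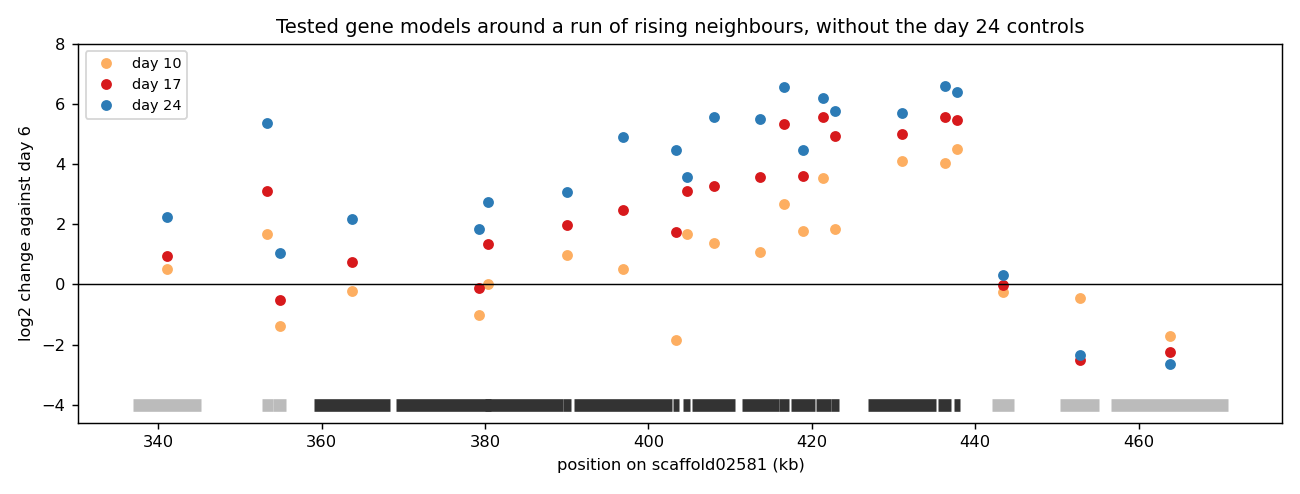
Log2 change against day 6 (vertical axis) of the tested gene models on scaffold02581 by position in kb (horizontal axis), without the 3 day 24 animals at concentration 0. Points are day 10, day 17 and day 24; blocks at the bottom are the gene models, dark for the 16 neighbours called higher at day 24, whose changes range from 1.85 to 6.61.

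Classes of gene models were also compared after the values were seen, and some of the differences changed with the day. Single-exon models rose at day 10 more often than the others. Of 1459 tested single-exon models 532 (36.5%) were higher at day 10, compared with 2533 of 11226 others (22.6%), an odds ratio of 1.97 (95% interval 1.75 to 2.21, Fisher's exact test across gene models, adjusted p = 4.6e-28). The difference was smaller at day 17 (20.2% against 17.2%, odds ratio 1.22, 95% interval 1.06 to 1.40, adjusted p = 0.0072). At day 24 it was 10.8% against 10.9% (odds ratio 0.984, 95% interval 0.820 to 1.17, adjusted p = 0.89), or 21.8% against 19.6% without the 3 libraries (adjusted p = 0.063). Of the single-exon models 189 (13%) were lower at day 24, against 3108 (27.7%) of the others, and without the 3 libraries 155 (10.6%) against 2188 (19.5%). They were lower less often at days 10 and 17 as well (odds ratios 0.694 and 0.640, and 0.389 at day 24). Models on contigs were higher less often than the others at days 10, 17 and 24 (odds ratios 0.657, 0.763 and 0.651, adjusted p at most 0.0025), and also without the 3 libraries (0.633, 0.741 and 0.623). Models on contigs fell more often than those on scaffolds at day 10: 300 of 1157 (25.9%) were lower, compared with 2078 of 11528 (18.0%) (odds ratio 1.59, 95% interval 1.38 to 1.83, adjusted p = 1.3e-09). At day 17 the shares were 16.6% and 15.1% (adjusted p = 0.22). At day 24 the difference was the other way, 20.4% against 26.6% (odds ratio 0.709, 95% interval 0.608 to 0.824, adjusted p = 6.9e-06), with an odds ratio of 0.821 (adjusted p = 0.024) without the 3 libraries. Gene models are not independent replicates, so these p-values describe the annotation's classes and not animals.

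Expression was next related to concentration, as the slope on concentration rank (0 to 6) averaged over days. APZ42_025466 (scaffold01877, 46062 to 46795, 2 exons) fell with rank: it averaged 7.15 ± 13 CPM (SD, n = 12) at concentration 0, 1.96 ± 5.91 at 1 nM Hg/L and 0.714 ± 1.04 at 4 nM Hg/L, with a slope of -0.59 log2 per rank (SE 0.14, adjusted p = 0.0031). Single animals carried much of these means: without the highest animal of each concentration they were 3.70, 0.253 and 0.481 CPM. APZ42_028475 (scaffold02413, 15 to 1663, 2 exons) fell from 12.5 ± 24.2 CPM (SD, n = 12) at concentration 0 to 1.82 ± 3.29 at 4 nM Hg/L, with a slope of -0.57 (SE 0.13, adjusted p = 0.0018); without the highest animals the means were 5.89 and 1.04 CPM. APZ42_017566 (scaffold00687, 1766030 to 1767498, 4 exons) rose, from 0.394 ± 0.596 CPM (SD, n = 12) at concentration 0 to 29.9 ± 57.1 at 1 and 17.8 ± 56.4 at 4 nM Hg/L, with a slope of 0.69 (SE 0.15, adjusted p = 0.0014). At 4 nM Hg/L 1 animal of day 24 had 196 CPM, and the mean of the other 11 was 1.52 CPM. At 1 nM Hg/L the mean without its highest animal was 15.8 CPM. APZ42_016252 (scaffold00604, 2240 to 3094, 3 exons) rose from 0.564 ± 1.45 CPM (SD, n = 12) to 16.2 ± 21.7 at 1 nM Hg/L, with 4.82 ± 13.2 at 4 nM Hg/L and a slope of 0.66 (SE 0.19, adjusted p = 0.013). It had 0 counts in the 3 day 24 animals at concentration 0, so that slope includes a fitted value for a group with no counts and gives no size. Without them the slope was 0.43. Its means without the highest animal of each concentration were 0.151 CPM at 0, 11.3 at 1 and 1.08 at 4 nM Hg/L. None of the 4 was monotone over the 7 concentrations: APZ42_025466 averaged 17.5 ± 31.1 CPM (SD, n = 12) at 0.25 nM Hg/L.

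The slope was called in 1798 of 12685 models, of which 1586 rose (88.2%) and 212 fell. With DESeq2 size factors, 73.5% of 1315 rose, with DESeq2 65.7% of 1276 and with limma-voom 59.8% of 1490. The count was 687 with the concentration itself as the score, which ended the calls of APZ42_017566 and APZ42_016252. It was 1175 with the older edgeR fit, which ended that of APZ42_016252, and 1069 without the filter. Without the day 24 animals at concentration 0, 1236 were called, 746 rising and 490 falling (868 when they were left out of the comparison only), and 816 models were called in both fits, 815 of them with the same sign. All 4 named models were called in both, and none of the 4 with limma-voom. With the day 24 animals at concentration 0 left out of the comparison only, APZ42_016252 was not called (edgeR, adjusted p = 0.052). The call of APZ42_017566 ended without replicate 1 of 4 nM Hg/L at day 17, and that of APZ42_025466 without replicate 3 of 0.015 nM Hg/L at day 17. That of APZ42_016252 ended without replicate 1 of 0.25 nM Hg/L at day 6, or of 4 nM Hg/L at day 17 or day 24.

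Averaged over days, 4 nM Hg/L differed from concentration 0 in 894 models, of which 830 were higher and 64 lower. The count was 200 with DESeq2, 209 in a fit of only the libraries compared, 297 with the older edgeR fit and 311 without the filter. The highest were APZ42_022094 (scaffold01348, 434875 to 437174, 4 exons), with 3.33 ± 3.27 CPM (SD, n = 12) at concentration 0 and 7.95 ± 3.66 at 4 nM Hg/L, and APZ42_023126 (scaffold01409, 308814 to 315877, 3 exons), with 3.44 ± 3.82 and 35.7 ± 47.4 CPM. APZ42_023126 lies in the stretch of scaffold01409 that rose after day 6. The lowest were APZ42_007021 (contig42504, 276 to 1194, 3 exons), with 13.7 ± 20 and 5.81 ± 11 CPM (SD, n = 12), and APZ42_004595 (contig25495, 1 to 1355, 3 exons), with 18.1 ± 18.3 and 7.80 ± 4.79 CPM. Without the highest animal of each concentration the means of these 4 models, in that order, were 2.82 and 7.43, 2.69 and 26.4, 9.46 and 3.74, and 13.2 and 7.05 CPM. Their log2 changes were 3.33 (SE 0.64, adjusted p = 6.1e-04), 2.92 (SE 0.92, adjusted p = 0.039), -2.78 (SE 0.80, adjusted p = 0.023) and -1.25 (SE 0.37, adjusted p = 0.027). APZ42_022094 had 0 counts in the 3 day 24 animals at concentration 0, so its averaged change includes a fold over a group with no counts and gives no size; at day 6 it averaged 6.73 ± 1.47 and 9.49 ± 4.29 CPM (SD, n = 3). Without the day 24 animals at concentration 0 none of these 4 calls held in the average over days 6, 10 and 17. The log2 changes were then 0.96 (SE 0.38, adjusted p = 0.22), 2.75 (SE 1.07, adjusted p = 0.21), -1.69 (SE 0.88, adjusted p = 0.37) and -1.22 (SE 0.42, adjusted p = 0.16), so APZ42_023126 and APZ42_004595 kept nearly the same change with a larger SE, and the other 2 changes shrank. In all 63 models were called (39 higher, 24 lower), of which 33 were among the 894, and 18 were called in that average with all libraries fitted. Of the 24 fits without 1 of the compared libraries, 12 ended the call of APZ42_023126: replicates 1, 2 and 3 of concentration 0 at day 6, 1 and 2 at day 10, 2 and 3 at day 17 and 3 at day 24, and, of 4 nM Hg/L, replicate 1 at day 6, 3 at days 10 and 17 and 1 at day 24. The call of APZ42_007021 ended without replicate 2 of concentration 0 at day 10, and that of APZ42_004595 without replicate 2 of concentration 0 at days 6, 10 or 17 or replicate 3 at day 24.

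The 5 lower concentrations were compared with concentration 0 in the same way. With all libraries 1143 models differed from concentration 0 at 0.015, 411 at 0.06, 239 at 0.12, 707 at 0.25 and 1849 at 1 nM Hg/L, with 91.3%, 96.8%, 95.8%, 93.8% and 89.8% of them higher; at 4 nM Hg/L 92.8% were higher. The older edgeR fit gave 451, 48, 4, 1.5e+02 (rounded to 2 digits) and 1092, a fit of only the libraries compared 217, 14, 1, 386 and 1229, and no filter 494, 85, 18, 258 and 1144. In the simulated data 71, 83, 58, 84 and 95 unchanged models were called in these averages. With DESeq2 size factors these shares were 79%, 82.7%, 75.9%, 73.2%, 72.7% and, at 4 nM Hg/L, 78.5%. Without the day 24 animals at concentration 0, in averages over days 6, 10 and 17, edgeR called 0 models at 0.015, 0.06, 0.12 and 0.25 nM Hg/L, with 1706, 470, 180 and 847 models at an unadjusted p below 0.05, and 162 at 1 nM Hg/L (33 of them lower), 144 of which were among the 1849. The same averages with all libraries fitted gave 0 at the 4 lowest concentrations (1503, 349, 167 and 706 at an unadjusted p below 0.05) and 130 at 1 nM Hg/L. The fall in these counts thus came with day 24 leaving the average, more than with the 3 libraries leaving the fit. With all libraries, DESeq2 called 164, 32, 23 and 102 models at the 4 lowest concentrations and 916 at 1 nM Hg/L, with 29.3%, 53.1%, 78.3%, 34.3% and 61.1% of them higher, and 56% at 4 nM Hg/L. The counts of limma-voom lay within 1.5 times of edgeR's except for 201 at 0.06 nM Hg/L. By limma-voom 40.8%, 59.2%, 56.5%, 47.9%, 50.1% and, at 4 nM Hg/L, 55.5% were higher, so at 0.015 and 0.25 nM Hg/L the majority was lower with both tools. The median log2 change over all models tested, which lay between 0.30 and 0.58 in these 6 averages, was lower by 0.09 to 0.17 with DESeq2 size factors. Single libraries moved some counts: at 0.015 nM Hg/L 648 models were called without its replicate 1 of day 10; at 0.06 nM Hg/L 629 without replicate 3 of concentration 0 at day 10, and 809 and 710 without its replicates 1 and 3 at day 24; at 0.12 nM Hg/L 585, 365 and 417 without replicates 1, 2 and 3 of concentration 0 at day 24.

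**Figure D4:**
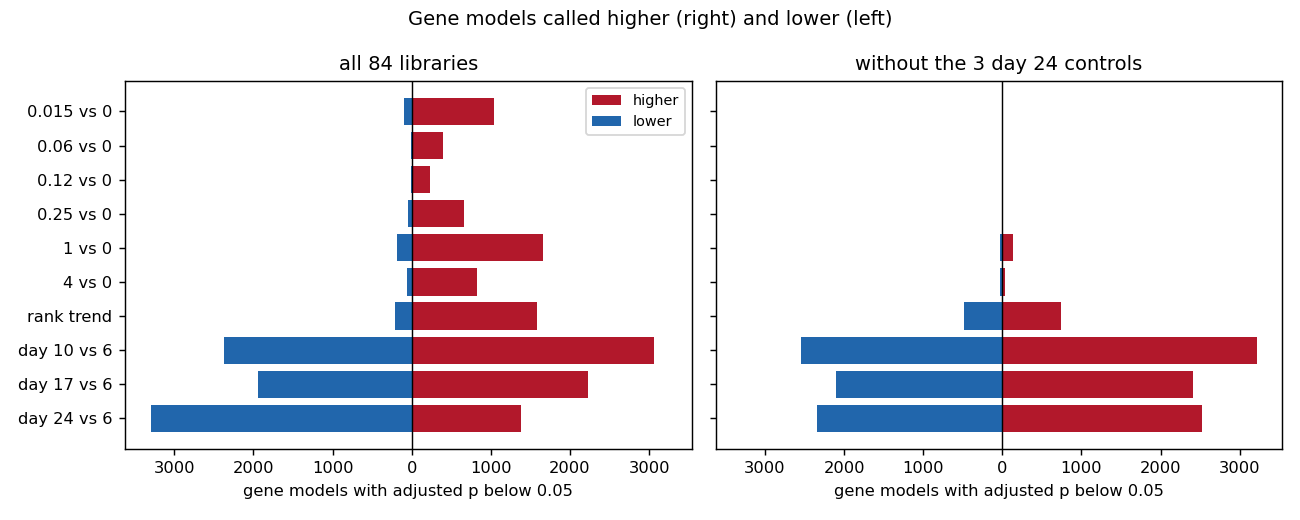
Number of gene models called at an adjusted p below 0.05 (horizontal axis), higher to the right and lower to the left, for each concentration in nM Hg/L against 0 averaged over days, the rank trend, and each day against day 6. The left panel uses all 84 libraries and the right panel leaves out the 3 day 24 animals at concentration 0: the counts against concentration 0 fell from between 239 and 1849 to between 0 and 162, and the day counts stayed between 4165 and 5758. The averages on the right cover days 6, 10 and 17.

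Within day 6, APZ42_034121 (scaffold03326, 427585 to 430369, 10 exons) was higher at 4 nM Hg/L than at concentration 0, from 0.220 ± 0.354 to 25.3 ± 24.4 CPM (SD, n = 3), as was APZ42_019722 (scaffold00944, 40559 to 42062, 6 exons), from 0.665 ± 0.846 to 48.6 ± 50.8 CPM. Lower were APZ42_018283 (scaffold00770, 58942 to 64068, 4 exons), from 8.81 ± 1.52 to 1.70 ± 1.81 CPM (SD, n = 3) and APZ42_014229 (scaffold00389, 695706 to 711330, 7 exons), from 18.7 ± 1.56 to 4.52 ± 3.26 CPM. Their log2 changes were 6.75 (SE 1.73, adjusted p = 0.025), 6.16 (SE 1.65, adjusted p = 0.035), -2.24 (SE 0.51, adjusted p = 0.0099) and -2 (SE 0.48, adjusted p = 0.015). The 2 rises came mostly from replicates 1 and 2 of 4 nM Hg/L, where 3.51% and 2.24% of counts lay outside the dominant models: APZ42_034121 had 25.3, 49.7 and 0.903 CPM in replicates 1, 2 and 3, and APZ42_019722 had 36.2, 104 and 5.26 CPM. In replicate 3, with 9.62% outside, they were nearer the highest animal at concentration 0 (0.628 and 1.63 CPM). The 2 falls were likewise less deep in replicate 3, which held most of the pooled counts of the falling models at 4 nM Hg/L. The ratios of pooled counts were 27.9 (95% counting interval 18.7 to 43.4) and 20.6 (16.3 to 26.5), and those of the falling models 0.357 (0.295 to 0.43) and 0.38 (0.335 to 0.43), all nearer to 1 than the log2 changes give. In all, 191 models were called, 30 of them lower, and the depth outside the dominant models was lower in the exposed group, as given above. The count was 47, 26 and 32 without replicate 1, 2 or 3 of concentration 0, and 71, 15 and 1118 without replicate 1, 2 or 3 of 4 nM Hg/L; with the log2 share outside the dominant models as a covariate it was 1, in a fit of only the libraries compared 1 and with 2 surrogate variables 7. It was 1205 with limma-voom (63% higher) and 318 without the day 24 animals at concentration 0 (61% higher), compared with 84.3% of the 191. Each of the 4 named calls ended without replicate 2 of concentration 0 and without replicate 1 or 2 of 4 nM Hg/L; those of APZ42_034121 and APZ42_019722 also ended without replicate 1 of concentration 0, and those of APZ42_019722, APZ42_018283 and APZ42_014229 without its replicate 3.

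At days 10 and 17 edgeR called 0 models for 4 nM Hg/L against concentration 0. The models at an unadjusted p below 0.05 numbered 1180 and 586. DESeq2 called 64 and 7 on those days and limma-voom 9 and 0. Among the lower concentrations, 1 nM Hg/L at day 10 gave 545 models, 417 higher and 128 lower, and 0.015 nM Hg/L at day 17 gave 2, both lower. The count for 1 nM Hg/L at day 10 was 1009 without the 5 libraries with low depth. It was at most 115 in a fit of only the libraries compared, which gave that many over all 20 contrasts of lower concentrations together. The other 13 contrasts of lower concentrations at days 6, 10 and 17 gave 0, with between 86 and 1074 models at an unadjusted p below 0.05. Over all 20 contrasts of the lower concentrations the calls summed to 10567, 91.9% of them higher, of which 547 came from the 15 contrasts at days 6, 10 and 17. Those 15 gave 804 without the day 24 animals at concentration 0. Over all 20, with DESeq2 size factors 72.1% of 5363 were higher. The majority was lower with DESeq2 (41.2% of 2435 higher), limma-voom (47.4% of 10207) and a fit of only the libraries compared (49 higher and 66 lower).

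At day 24 the comparison with concentration 0 rests on the 3 shallow libraries. APZ42_023136 (scaffold01409, 330049 to 348997, 3 exons), which lies in the stretch of that scaffold that rose after day 6, had 0 counts in them and 52.6 ± 89.9 CPM (SD, n = 3) at 4 nM Hg/L, at least 37.0-fold higher. APZ42_020705 (scaffold01005, 856843 to 862440, 15 exons) had 0 counts in them and 32.5 ± 55.8 CPM (SD, n = 3), at least 22.9-fold higher. Both means and both bounds rest on replicate 1 of 4 nM Hg/L, which had 3050 and 1890 counts. The bounds use TMM-scaled library sizes and cover no error of that scaling. Under it the median log2 change over all models tested was 1.80 in this comparison, and 1.24 with DESeq2 size factors. Replicates 2 and 3 had 0.403 and 0.970 CPM of APZ42_023136 and 0.220 and 0.299 CPM of APZ42_020705. These lie under the floor of 1.38 CPM at concentration 0 and give no fold. Both calls ended without that replicate, and also without any 1 of the 3 replicates at concentration 0. APZ42_013494 (scaffold00276, 176 to 1294, 1 exon) had 34 counts at concentration 0, 17.7 ± 10.6 CPM (SD, n = 3), and 0 at 4 nM Hg/L, at least 313-fold lower. APZ42_005322 (contig29234, 1 to 319, 1 exon) had 383 counts at concentration 0 and 1 count at 4 nM Hg/L, a ratio of 4 nM Hg/L over 0 of 9.44e-05 (95% counting interval 2.38e-06 to 0.000529). Both were also raised at 0.12 nM Hg/L on day 24, the next lowest group in depth, with 1.43 ± 0.438 CPM (SD, n = 3) for APZ42_013494 and 6.80 ± 1.5 for APZ42_005322. In each of the other 26 groups both averaged at most 0.153 CPM. The 4 adjusted p-values were 0.037, 0.022, 2.3e-06 and 7.9e-08.

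In all, 2385 models were called for 4 nM Hg/L against 0 at day 24, 2171 higher (91%) and 214 lower, with a median log2 change of 1.80 over all models tested, or 1.24 with DESeq2 size factors. With DESeq2 size factors 71.2% of 1305 were higher, with DESeq2 20.1% of 299, and with limma-voom 41.8% of 2046, and a fit of only the libraries compared called 11, 0 higher and 11 lower, so the direction of the majority was not stable. The count was 678 with the older edgeR fit, 849 with the share outside the dominant models as a covariate, 1458 without the filter and 1498 with 2 surrogate variables. The lower concentrations at day 24 gave 2103 calls at 0.015, 1865 at 0.06, 1568 at 0.12, 2212 at 0.25 and 2272 at 1 nM Hg/L against the same 3 animals.

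Any difference among the 7 concentrations was called in 427 models at day 6, 813 at day 10, 714 at day 17 and 3023 at day 24. Limma-voom called 1545, 2422, 2939 and 1438, and 2 surrogate variables gave 201, 1004, 263 and 1382. DESeq2 gave 445, 1606, 1068 and 1480, and a fit of only the libraries compared 428, 276, 780 and 233. Among the 6 exposed concentrations at day 24, without concentration 0, 1598 models differed. With all libraries fitted this count was 1062, and without the 5 libraries with low depth it was 1104. The day 10 count was 433 without replicate 3 of 1 nM Hg/L and 1.1e+02, rounded to 2 digits, without its replicate 1. The day 6 count was 250 without replicate 2 of 0.12 and 266 without replicate 2 of 4 nM Hg/L. The slope on concentration rank differed between days in 1661 models (2060 with limma-voom, 1054 with the older edgeR fit, 910 without the filter, 702 with 2 surrogate variables, 616 with DESeq2 and 332 with the share outside the dominant models as a covariate). It differed in 392 without the day 24 animals at concentration 0 and in 237 with these out of the comparison only. Without the 5 libraries with low depth it differed in 191.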

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

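Of the tests in this part, those of expression that follows the share outside the dominant models, and the look at where the splits put the shallow libraries, were chosen after the result was seen. The slope on concentration rank differed between days in 1661 models by a joint test of the difference, and in 392 without the day 24 animals at concentration 0. The count was 237 with these out of the comparison only and 191 without the 5 libraries with low depth. Of 100 splits of the libraries 1, the real one, gave as many as 1661 (highest other 533). Those splits mix the shallow day 24 controls among the concentrations, whereas the real grouping holds them together. That share thus cannot tell a difference between days in the effect of concentration from those controls. Without the day 24 animals at concentration 0, 2 of 100 did for 392, and the highest other split gave 576.

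The first pattern is the 2385 models called for 4 nM Hg/L against concentration 0 at day 24. The libraries of 1 nM Hg/L, thinned to the depth of those controls, gave 451 calls against 4 nM Hg/L (404 to 490 over 5 draws, 18.9% of 2385; 0 before thinning), which leaves open how much of the count low depth may account for. Expression that follows a low share outside the dominant models was gauged by within-group slopes on the log2 share, relative to the uncalled models. For the 2171 higher models the median slope was 0.17, against 0.2 in the uncalled ones, and the median log2 change 2.93 against 1.38. That difference in slope carried -7.85% (bootstrap interval -12.4 to -1.26) of the difference in change from the uncalled models. For the 214 lower models it carried 62.2% (51.8 to 73.2). The bootstrap resampled gene models and not animals, so both intervals leave out the spread between animals. This explanation stays open for both, as within-group slopes were extended to a share difference of 4.10 log2 units and animals of the same group differed by at most 2.10. The 10 splits of the 6 libraries are too few for a share under 0.05, and 1 of them, the real one, gave as many as 2385 (highest other 25). An effect of coal ash, and of the state of the 3 controls themselves, stays open and untested, because no other day 24 animals at concentration 0 were analysed here.

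The second pattern is the 191 models called for 4 nM Hg/L against concentration 0 at day 6. Within-group slopes on the share outside the dominant models were again taken relative to the uncalled models. They carried 32.6% (26.4 to 36.9) of the difference in change between the higher and the uncalled models. For the 30 lower ones they carried 28% (16.9 to 45.1). These bootstrap intervals also resample gene models and not animals. The values neither exclude that expression followed the share nor show whether this accounts for the change. With the log2 share as a covariate 1 model was called. The 10 splits are too few for a share under 0.05, and 1 of them, the real one, gave as many as 191 (highest other 31). The low share was in replicates 1 and 2 of 4 nM Hg/L (3.51% and 2.24%), whereas replicate 3 had 9.62%, near the 9.99% to 13.5% at concentration 0; 1 such animal decides nothing, so an effect of coal ash and one of the low share both stay open.

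For each concentration against 0 averaged over days, a share under 0.05 of 100 splits gave as many models as the real grouping. The splits mix the 3 shallow day 24 controls among the concentrations, whereas the real grouping holds them together at concentration 0. A low share thus cannot tell an effect of concentration from those 3 libraries. 1 split, the real one, gave as many models at 0.015 (1143, highest other 712), 0.06 (411, highest other 73), 0.25 (707, highest other 119), 1 (1849, highest other 315) and 4 nM Hg/L (894, highest other 120). At 0.12 nM Hg/L 2 splits did, so a shuffled grouping can exceed the real count. The other split gave 920 against the real 239, several times as many. That split kept 2 of the 3 shallow day 24 controls at concentration 0 and put none at 0.12 nM Hg/L, and the split with 712 put all 3 at 0.015 nM Hg/L; whether they made these counts was not tested. Without the day 24 animals at concentration 0, in averages over days 6, 10 and 17, 2 of 100 splits gave as many at 1 nM Hg/L (162, highest other 470, again several times the real count) and 2 at 4 nM Hg/L (63, highest other 81).

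For the trend 1 of 100 splits, the real one, gave as many (1798, highest other 62), and so did 1 of 100 without those animals (1236, highest other 405). Where the day 24 controls take part, the splits mix them as well, with the same limit. The same held for the 20 contrasts of lower concentrations (1 of 100, 10567, highest other 6609). It held for any difference among concentrations at day 6 (1 of 100, 427, highest other 385), day 10 (1 of 100, 813, highest other 801), day 17 (1 of 100, 714, highest other 247) and day 24 (1 of 100, 3023, highest other 1333), closely at days 6 and 10. In these joint tests the median of the other splits was 171, 121, 63 and 167 models at days 6, 10, 17 and 24, so the real counts do not number the models beyond chance. It held for day 10 (1 of 100, 5443, highest other 1855), day 17 (1 of 100, 4165, highest other 723) and day 24 against day 6 (1 of 100, 4680, highest other 987). For 4 nM Hg/L against 0 at days 10 and 17 all 10 splits gave 0 calls by edgeR, as the real one did, with 1180 and 586 models at an unadjusted p below 0.05, DESeq2 counts of 64 and 7 and limma-voom counts of 9 and 0; 10 splits are too few for a share under 0.05.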

How the results depend on the processing

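Of the settings in this part, the older edgeR fit, the removal of the dominant models, both sets of left-out libraries, the comparisons without the day 24 controls and the share as a covariate were chosen after the result was seen. The counts for days 10, 17 and 24 against day 6 stayed within 1.5 times of those reported under every setting run for them, and removing the 5 dominant models kept all 20 counts within that bound. None of these settings separated the day from the depth of its libraries. Other counts are given below where they moved further, with values written with an exponent rounded to 2 digits, and the cause not tested except that fits with fewer libraries compare fewer samples. The majority among the calls changed direction in several results. With DESeq2 it was 48 higher and 116 lower for the 0.015 average, 35 and 67 for the 0.25 average, 60 and 239 for 4 against 0 at day 24, 1004 and 1431 for the lower concentrations within days and 2455 and 1878 for day 24 against day 6. Limma-voom gave 498 and 723, 393 and 427, 856 and 1190, 4843 and 5364, and 2965 and 2524 for the same results. A fit of only the libraries compared gave 0 and 11 for 4 against 0 at day 24, 0 and 1 at day 6, and 49 and 66 for the lower concentrations within days. Leaving out the day 24 controls gave 2522 and 2343 for day 24 against day 6 (2323 and 2245 when left out of the comparison only), and leaving out the 5 libraries with low depth gave 3 and 7 for the 4 average, 3008 and 3028 for day 10 and 2277 and 2293 for day 17. Averages over days against concentration 0, and comparisons with it at day 24, depend on the 3 shallow controls. Leaving them out, alone or among the 5, removes those animals as well as their depth. It also leaves averages over days 6, 10 and 17, so the counts without them do not separate the causes. The lower concentrations then make 15 contrasts in place of 20, which gave 547 with all libraries fitted, so 804 and 1015 below are higher counts for the same contrasts. An average is a concentration in nM Hg/L against 0 averaged over days.

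With DESeq2 size factors the counts were 519 for the 0.015 average, 98 for the 0.06 average, 54 for the 0.12 average, 269 for the 0.25 average, 465 for the 4 average and 1305 for 4 against 0 at day 24. It also gave 964 for the trend differing between days and 5363 for the lower concentrations within days. Without a filter on low counts they were 494 for the 0.015 average, 85 for the 0.06 average, 18 for the 0.12 average, 258 for the 0.25 average, 1144 for the 1 average and 311 for the 4 average. It also gave 1.2e+02 for 4 against 0 at day 6, 1458 for 4 against 0 at day 24, 1937 for any difference at day 24, 1069 for the trend, 910 for the trend differing between days and 5918 for the lower concentrations within days. DESeq2 gave 164 for the 0.015 average, 32 for the 0.06 average, 23 for the 0.12 average, 102 for the 0.25 average, 916 for the 1 average and 200 for the 4 average. It also gave 64 for 4 against 0 at day 10, 7 for 4 against 0 at day 17, 299 for 4 against 0 at day 24, 1606 for any difference at day 10, 1480 for any difference at day 24 and 616 for the trend differing between days. The same setting gave 2435 for the lower concentrations within days. Limma-voom gave 201 for the 0.06 average, 1205 for 4 against 0 at day 6, 9 for 4 against 0 at day 10, 1545 for any difference at day 6, 2422 for any difference at day 10 and 2939 for any difference at day 17. The same setting gave 1438 for any difference at day 24. A fit of only the libraries compared gave 217 for the 0.015 average, 14 for the 0.06 average, 1 for the 0.12 average, 386 for the 0.25 average, 1229 for the 1 average and 209 for the 4 average. The same setting gave 1 for 4 against 0 at day 6, 11 for 4 against 0 at day 24, 276 for any difference at day 10, 233 for any difference at day 24 and 115 for the lower concentrations within days. With 2 surrogate variables there were 413 for the 0.015 average, 7 for 4 against 0 at day 6, 11 for 4 against 0 at day 10, 1498 for 4 against 0 at day 24, 201 for any difference at day 6 and 263 for any difference at day 17. The same setting gave 1382 for any difference at day 24 and 702 for the trend differing between days. Concentration itself as the score gave 687 for the trend. The older edgeR fit gave 451 for the 0.015 average, 48 for the 0.06 average, 4 for the 0.12 average, 1.5e+02 for the 0.25 average, 1092 for the 1 average and 297 for the 4 average. It also gave 678 for 4 against 0 at day 24, 284 for any difference at day 6, 1981 for any difference at day 24, 1175 for the trend, 1054 for the trend differing between days and 2632 for the lower concentrations within days. The share outside the dominant models as a covariate gave 677 for the 0.015 average, 315 for the 0.25 average, 1177 for the 1 average, 1 for 4 against 0 at day 6, 1 for 4 against 0 at day 10 and 849 for 4 against 0 at day 24. It also gave 188 for any difference at day 6, 1203 for any difference at day 24, 332 for the trend differing between days and 5778 for the lower concentrations within days. Leaving the 3 animals of concentration 0 at day 24 out of the comparisons only gave 0 for the 0.015 average, 0 for the 0.06 average, 0 for the 0.12 average, 0 for the 0.25 average, 130 for the 1 average and 18 for the 4 average. It also gave 1062 for any difference at day 24, 868 for the trend, 237 for the trend differing between days and 547 for the lower concentrations within days. Leaving out the 3 animals of concentration 0 at day 24 gave 0 for the 0.015 average, 0 for the 0.06 average, 0 for the 0.12 average, 0 for the 0.25 average, 162 for the 1 average and 63 for the 4 average. It also gave 318 for 4 against 0 at day 6, 1598 for any difference at day 24, 392 for the trend differing between days and 804 for the lower concentrations within days. Leaving out the 5 libraries with low depth gave 0 for the 0.015 average, 0 for the 0.06 average, 0 for the 0.12 average, 0 for the 0.25 average, 194 for the 1 average and 10 for the 4 average. It also gave 29 for 4 against 0 at day 6, 1 for 4 against 0 at day 17, 253 for any difference at day 6, 1104 for any difference at day 24, 191 for the trend differing between days and 1015 for the lower concentrations within days. The 4 averages at 0 by edgeR had 1808, 553, 189 and 967 models at an unadjusted p below 0.05 without the 5 libraries, and 1706, 470, 180 and 847 without the 3, and 1503, 349, 167 and 706 with the 3 out of the comparisons only; no other tool was run on these subsets.

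Leaving out each library in turn gave 648 to 1625 for the 0.015 average, 329 to 809 for the 0.06 average, 1.7e+02 to 585 for the 0.12 average, 548 to 935 for the 0.25 average, 1559 to 2062 for the 1 average, 711 to 1293 for the 4 average and 15 to 1118 for 4 against 0 at day 6. Ranges for other results were 250 to 577 for any difference at day 6, 1530 to 2163 for the trend, 1356 to 2258 for the trend differing between days, 5071 to 5664 for day 10 against day 6, 3870 to 4201 for day 17 against day 6, 4106 to 4925 for day 24 against day 6 and 9791 to 11546 for the lower concentrations within days. The remaining ranges were 0 to 0 for 4 against 0 at day 10, 1.1e+02 to 1080 for any difference at day 10, 0 to 0 for 4 against 0 at day 17, 499 to 839 for any difference at day 17, 1924 to 2291 for 4 against 0 at day 24 and 2652 to 3529 for any difference at day 24.

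Of 28 named results the direction held under each setting. Calls were lost for 1 with DESeq2, 3 with DESeq2 size factors, 5 without the filter, 6 each with 2 surrogate variables and the older fit, 8 in a fit of only the libraries compared, 9 each with limma-voom and the covariate, and 2 of 4 with concentration itself as the score. Calls were lost for 4 of 24 without the day 24 controls, all in the 4 average, for 5 of 24 with these out of the comparisons only, and for 9 of 24 without the 5 low libraries. The 12 results of the day contrasts kept their calls under every setting, and of 936 leave-one-out fits of named results 47 fell below the threshold. Where 1 library was left out, its group of 2 shared the spread estimated from all groups. No value for 4 against 0 at day 24 exists without its controls. No paired analysis was possible because replicate numbers only name the libraries. Set tests of the planned gene lists were not run, since no list could be formed.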

Other observations

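The test of the axis in this part was written before its result was seen, and the axis was examined after the data were seen. Animals of the same group differed most along 1 axis, which held 17.7% of the within-group variance over 79 libraries (the 5 shallow ones left out); the next axes held 16.7% and 7.4%. On one side lay APZ42_004437 (contig24833, 1 to 1641, 1 exon), which reached 321 CPM (correlation with the axis within groups 0.87), and APZ42_025438 (scaffold01877, 48452 to 49665, 2 exons), which reached 308 CPM (0.84) and lies beside APZ42_025466, a model named for its trend. On the other side lay APZ42_034076 (scaffold03326, 310052 to 313185, 4 exons), between 0.127 and 675 CPM (-0.92), and APZ42_034078 (scaffold03326, 343472 to 352966, 7 exons), between 0 and 153 CPM (-0.92). Both lie on the scaffold of APZ42_034082, which rose by day 17, and of APZ42_034121, which was higher at 4 nM Hg/L on day 6. These 4 were chosen after their values were seen. Over the 79 libraries 71 models had a within-group correlation with the axis above 0.7 and 357 one below -0.7, across models that are not independent replicates.

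The third pattern is this axis, whose root mean square score was 13.2 at day 6, 32.0 at day 10, 33.7 at day 17 and 38.7 at day 24; the days were not tested against each other. The day 6 value rests on the 0.12 nM Hg/L group, whose replicate 2 stood apart at -44.4: without that group it was 5.5, and without the group farthest apart on each of the other days 28.4, 30.2 and 34. A low share outside the dominant models is a candidate explanation that the test argued against: Spearman's rho of axis score and log2 share within groups was 0.07 (bootstrap interval -0.15 to 0.30, permutation p = 0.52, n = 79) and Pearson's r 0.10 (permutation p = 0.36), or 0.09 without the 2 libraries farthest from the median share. Within days 6, 10, 17 and 24 rho was 0.33, 0.19, -0.23 and 0.32 (permutation, adjusted p = 0.41 each over 4 days). Scores and shares were deviations from group means, which are not independent within a group. The bootstrap and the permutations did not take this into account, so the interval and p-values are approximate. The test covers this axis and these 79 libraries only, since the shallow ones were left out and the next axes were not set against the share. The stage of each animal in its moult or brood cycle stays a possible explanation that was not tested, as no label used here gives it per library.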
